A study of Mus musculus with 2 samples.

How the data were processed

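Single-cell RNA was measured by 3′ droplet sequencing (10x Genomics Chromium) in live CD45+ cells that were sorted by flow cytometry from dissociated tumours of C57BL6\J mice. All mice had been ovariectomised. The placebo group and the E2 group each held 1 library, so 2 libraries were analysed. The tumour type, the dose and duration of E2 and the number of mice behind each library are not given in the sources used here.

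The deposited values are raw counts of unique molecular identifiers (UMIs) per gene and barcode, with no normalization. The authors made these counts with Cell Ranger 3.1.0 on the mouse genome build mm10, per the submitters' processing notes, and the same version stands in the matrices, per the file headers. The barcodes are a filtered set, with no barcode under 500 UMIs, and the rule that chose them is not given in the sources used here. Each matrix lists 47730 features, of which 47224 matched the GENCODE M21 annotation of GRCm38 (the assembly that mm10 names) by gene identifier. Coordinates were taken from that annotation and are 1-based. The 37 mitochondrially encoded features held 0 UMIs in both libraries, so the mitochondrial filter removed no barcode and no mitochondrial share could be used to judge cell quality.

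The placebo library held 3505 barcodes and 24545595 UMIs, and the E2 library held 5791 barcodes and 52628133 UMIs. Barcodes with under 200 genes were removed, 15 in the placebo library and 26 in the E2 library, and the limit on mitochondrial UMIs was 10%. Scrublet scores were computed within each library with scanpy 1.11.5. The automatic threshold marked 0.0856% of placebo barcodes and 1.49% of E2 barcodes, so it separated few doublets in the placebo library. As planned, the barcodes with the highest scores were removed at 0.8% per 1000 barcodes instead, 98 in the placebo library and 268 in the E2 library. This left 3392 and 5497 barcodes, with medians of 5089 and 7885 UMIs.

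The kept barcodes of both libraries were normalized, log-transformed and clustered together, with no batch correction, on 2000 variable genes, 30 principal components and 15 neighbours, with the Leiden algorithm (leidenalg 0.10.2, igraph 0.11.9) at resolution 1. The 36 clusters were named from 25 fixed lists of marker genes. A name needed at least 3 markers that were higher in the cluster, and it was withheld where the 10 leading genes of the cluster pointed to another class or where the cluster was shallow, with a median UMI count under the library median divided by 3, and had no marker of its name among its leading genes. Monocytes and macrophages were kept as 1 class, and 5 clusters stayed unnamed. A class is called X-like because its name rests on marker genes, and 1 marker gene was not found under its symbol.

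UMIs were summed over the cells of a class in each library and scaled to a common total, as CPM. Genes are described by log2((CPM E2 + 10)/(CPM placebo + 10)), which understates the ratio of low genes, and by the ratio of the CPM with its exact conditional-binomial 95% interval. Shares carry exact (Clopper-Pearson) 95% binomial intervals. These intervals cover counting error only. With 1 library per group there is no estimate of the spread between mice or libraries, so no test was run and no p-value was computed. A gene list was summarised by the median log2 ratio of its members with at least 20 UMIs over both libraries, in classes with at least 100 cells in each library. The percentile of that median among 10000 random lists of the same size, matched on mean expression in 20 bins, is a description of these libraries. Shares of cells with a UMI were computed after thinning each cell to 2000 UMIs, with shallower cells left out. Numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0 were used in Python 3.11.15, and plots were drawn with matplotlib 3.10.9.

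Named genes had at least 50 CPM in a library and at least 30 UMIs over both. Ribosomal protein genes, mitochondrially encoded genes, antigen receptor variable segments and gene models named Gm or Rik were left out. Ranked by log2 ratio, the 12 highest and 12 lowest were named in the class with most cells, and the 6 highest and 6 lowest in each of the next 4 classes. For each gene list, up to 5 members with the largest absolute log2 ratio could be named as well. In T-like cells, 1 gene that this rule names is not reported here. The groups, the lists, the naming rule, the summaries and most alternatives were chosen before the data were examined. A further 3 alternatives were chosen after seeing the data: adding the unnamed clusters of usual depth to the monocyte/macrophage class, shares among named immune classes only, and the same cluster mix in both libraries, in which clusters with at least 30 cells in each library were weighted alike.

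The ratio intervals were tested on simulated counts with known changes, drawn with counting (Poisson) error from the gene means over both libraries. The interval assumes that same error, and the draws held no spread between cells. The rates below therefore check the calculation and do not show how the intervals cover real cells. For E2 against placebo at the depth of a whole library, the interval held the simulated ratio for 95.7% of 16522 genes. At this depth it excluded no change on the right side for 81.8% of 66 genes changed 1.5-fold, 94.0% of 67 genes changed 2-fold and 100% of 62 genes changed 4-fold. At 10% of that depth it held the ratio for 95.8% of 11409 genes, and it excluded no change for 60.3% of 63 genes changed 1.5-fold. Neutrophil-like, NK-like and cDC2-like cells had fewer placebo UMIs than 10% of the placebo library, 612003, 652826 and 1437288. So did the regulatory T-like, CD4 T-like and CD8 T-like subsets, with 2422156, 1143735 and 922829. T-like cells had 4540835 E2 UMIs, fewer than 10% of the E2 library. The simulated rates do not extend to classes that small.

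The alternatives varied the cell filters, the doublet removal, the clustering resolution, thinning of every cell to 2000 UMIs before clustering, the scaling, the pseudocount, the weighting of cells and the gene minimum. The counts were not corrected for free RNA in droplets. A list with fewer than 3 members past the gene minimum in a class was given no median.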

Results

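Immune cells that had entered tumours were profiled by single-cell RNA sequencing in ovariectomised mice given placebo or E2, the usual abbreviation of estradiol, the main ovarian estrogen. Ovariectomy removes most of the estrogen a female mouse makes, so the comparison asks how the immune cells of a tumour differ between a host with and a host without added estrogen. Live cells carrying CD45, a surface protein of nearly all white blood cells, were sorted before the libraries were made. Each group held 1 library. The placebo library had 3505 barcodes, 24545595 UMIs and a median of 5128 UMIs and 2076 genes per barcode. The E2 library was deeper, with 5791 barcodes, 52628133 UMIs and medians of 8049 UMIs and 2552 genes. After filtering, 3392 placebo and 5497 E2 barcodes were compared. Every difference below is a difference between these 2 libraries and has no replicate check.

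The E2 library held a smaller share of lymphoid cells and a larger share of myeloid cells than the placebo library. T-like cells made up 30.2% of placebo barcodes (95% interval 28.7 to 31.8%) and 15.9% of E2 barcodes (15 to 16.9%), 1.90-fold lower in the E2 library. Monocyte/macrophage-like cells made up 26.0% (24.6 to 27.5%) and 34.9% (33.6 to 36.2%). The conventional dendritic cells that present antigen to T cells were also more frequent in the E2 library. Type 1-like conventional dendritic cells (cDC1-like), known for presenting antigen to CD8 T cells, were 1.98% of placebo and 5.68% of E2 barcodes, 2.87-fold higher. Type 2-like conventional dendritic cells (cDC2-like), known for presenting antigen to CD4 T cells, were 3.18% and 6.35%.

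Among rarer classes, B-like cells were 5.13% of placebo barcodes (4.41 to 5.93%) and 1.0% of E2 barcodes (0.755 to 1.30%). Much of this difference lay in cluster 24, led by Vpreb3, which held 108 placebo and 3 E2 cells. The other B-like cluster, 21, was 1.95% (1.51 to 2.47%) and 0.946% (0.707 to 1.24%), 2.06-fold lower. Type 2 innate lymphoid-like cells (ILC2-like), sources of interleukin 5 and interleukin 13, were 3.95% and 1.31%, 3.02-fold lower. Basophil-like cells, circulating granulocytes that make interleukin 4, were 3.21% (2.65 to 3.86%) and 0.546% (0.369 to 0.778%), 5.89-fold lower. Mast-like cells, tissue-resident granule cells, lay on the other side at 1.80% (1.38 to 2.30%) and 4.13% (3.62 to 4.69%), 2.30-fold higher. Neutrophil-like cells were 7.61% and 9.86%, and plasmacytoid dendritic-like cells 0.767% and 1.38%. The shares of NK-like cells, 3.07% and 2.58%, and of CCR7+ mature dendritic-like cells, 2.59% and 2.57%, had overlapping intervals. The 5 unnamed clusters together held 9.49% of placebo and 10.7% of E2 barcodes.

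Shares within each lineage leave out part of this trade-off. Of the cells in named immune classes, lymphoid classes were 47.3% (45.5 to 49.1%) in the placebo library and 24.1% (22.9 to 25.4%) in the E2 library. Within the named myeloid cells, monocyte/macrophage-like cells were 55.2% and 53.3%, so their larger overall share did not come with a larger share of the myeloid compartment. In that compartment cDC1-like cells were 4.19% and 8.68%, and basophil-like cells 6.81% and 0.835%. Within the named lymphoid cells, NK-like cells were 7.24% and 12.4%, and B-like cells, the Vpreb3-led cluster included, 12.1% and 4.81%. Among T-like cells, the regulatory T-like subset, which restrains other T cells, was 46.5% and 49.3%. The CD4 T-like subset was 26.0% and 19.1%, the CD8 T-like subset 17.9% and 13.8%, and the gamma-delta T-like subset, T cells with an alternative antigen receptor, 7.22% and 12.8%.

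**Figure D1:**
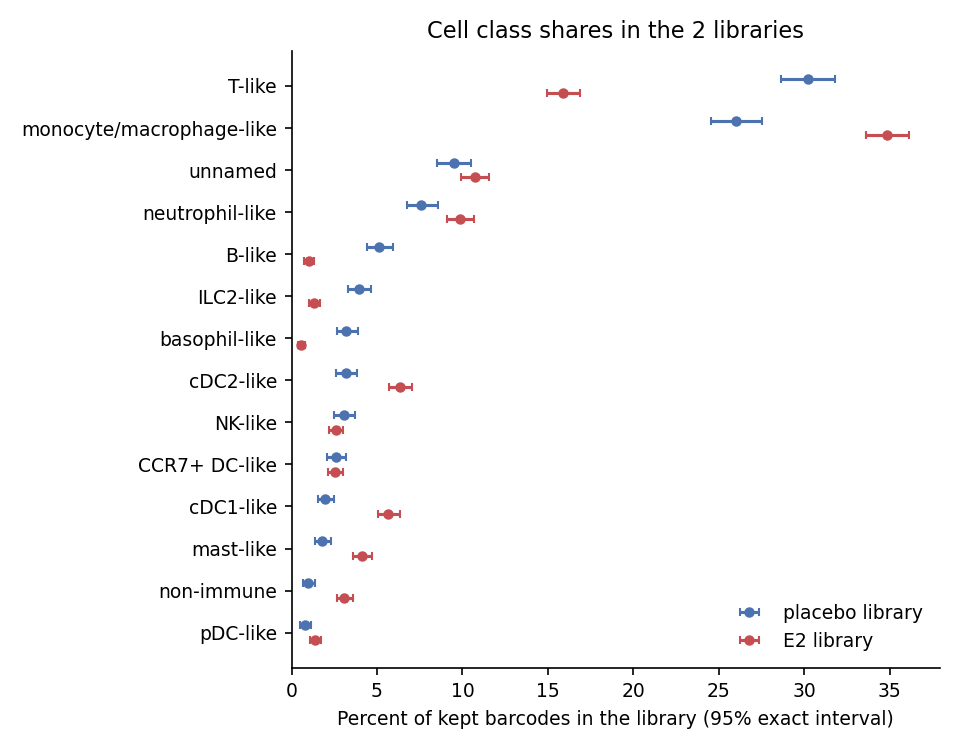
Percent of kept barcodes in each cell class (x axis) in the placebo library (blue) and the E2 library (red), with exact 95% intervals that cover counting error only. T-like cells lie at 30.2% in the placebo library and 15.9% in the E2 library, and monocyte/macrophage-like cells at 26.0% and 34.9%.

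The sort sets the range of these shares, and barcodes outside it remained: clusters of fibroblast, endothelial, keratin-expressing and glial-like cells, together called non-immune, were 0.973% of placebo and 3.09% of E2 barcodes. The unnamed cluster 17, which had Krt71 and Krt25 among its leading genes and in which 1.02% of barcodes had a UMI of Ptprc, the CD45 gene, lay the other way at 4.25% and 0.964%, so no direction is given for all barcodes outside the sort. The log2 ratio of B-like shares, -2.36, was -1.02 with no doublet removal, where a further cluster of 79 placebo and 158 E2 barcodes, with a median of 1122 UMIs, took the B-like name. That of basophil-like shares, -2.56, was -3.94 with 3 times as many doublets removed.

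Within monocyte/macrophage-like cells the lists of lipid-handling and of complement C1q genes were higher in the E2 library, and those of hypoxia and matrix remodelling genes were lower. With the same cluster mix in both libraries, the hypoxia, matrix remodelling and C1q medians lay within the middle 95% of random lists. The lipid-handling median stayed above that range. Chil3 (chromosome 3, 106147554 to 106167564, minus strand), a chitinase-like secreted protein of monocytes and alternatively activated macrophages, was at 277 CPM in the placebo library and 1450 CPM in the E2 library, 5.23-fold higher (95% interval 5.01 to 5.46). Arg1 (chromosome 10, 24915221 to 24927484, minus strand), the arginase that depletes arginine, was at 743 and 106 CPM, 7.04-fold lower (6.68 to 7.41). Apoe (chromosome 7, 19696109 to 19699188, minus strand), a lipid carrier protein, was at 6269 and 13697 CPM, 2.18-fold higher (2.16 to 2.21). Its receptor partner Trem2, a lipid-sensing receptor of macrophages, was at 189 and 429 CPM, 2.27-fold higher (2.15 to 2.39).

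Chil3, Arg1 and Apoe are leading genes of monocyte/macrophage-like clusters 2, 4 and 1, and the libraries filled these clusters unequally. Cluster 1 held 243 placebo and 570 E2 cells, cluster 2 174 and 424, cluster 3 100 and 464, cluster 4 280 and 219, cluster 12 72 and 189, and cluster 28 14 and 51. Values within clusters are therefore given for the clusters these genes do not define. The Chil3 log2 ratio was 2.69 in cluster 1, 2.66 in cluster 3 and 1.06 in cluster 4. Arg1 lay at -1.76 in cluster 1, -1.55 in cluster 3 and -0.38 in cluster 2. These clusters held at most 139 CPM of Arg1 in the placebo library, against 1921 placebo and 554 E2 CPM in cluster 4. How much of their Arg1 was free RNA from other cells was not tested. Apoe lay at 1.17 in cluster 2, 1.31 in cluster 4 and 0.21 in cluster 3. Trem2, which leads none of the clusters, was higher in the E2 library in clusters 1 to 4, with log2 ratios of 0.53, 0.96, 0.46 and 1.49. Gdf3, a growth factor of the TGF-beta family, was at 13 and 58.1 CPM, with log2 ratios of 1.38, 1.17, 1.13 and 1.55 in clusters 1 to 4. Qsox1, a secreted enzyme that forms disulfide bonds, was at 52.6 and 14.9 CPM and lay at -1.29, -0.87, -1.98 and -1.15.

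The other genes with the highest ratios were Fcrls, S100a9, S100a8, Pf4, Folr2, Cbr2, Ccl8 and Gas6, with log2 ratios from 1.12 to 2.19. Folr2, a folate receptor of tissue-resident macrophages, was at 15.5 and 57.9 CPM, but nearly all of it lay in cluster 3, at 198 and 253 CPM there, 1.28-fold higher (1.06 to 1.55). Fcrls, Pf4, Cbr2, Ccl8 and Gas6 lead cluster 3, and with the same cluster mix in both libraries Cbr2 was at 0.11, Gas6 at -0.08 and Ccl8 at -0.23. Outside cluster 3, Fcrls lay at 1.41, 0.17 and 1.75 and Pf4 at 1.39, 0.11 and 2.02 in clusters 1, 2 and 4. The alarmins S100a8 and S100a9 are abundant in neutrophils, and neutrophil-like cells held 63045 and 70397 CPM of them, 751 and 1698 times the level in this class. The other genes with the lowest ratios were Cxcl3, Pdpn, Ccl24, Cdh1, Mmp13, Inhba, AA467197, Slc7a2, Timp1 and Hilpda, from -2.00 to -1.34. Ccl24, an eosinophil-attracting chemokine, was at 707 and 171 CPM, 4.14-fold lower (3.96 to 4.33). Inhba, which encodes the activin A subunit, was at 53.2 and 9.63 CPM, 5.52-fold lower (4.62 to 6.61). Cdh1, the adhesion protein E-cadherin, was at 113 and 22.3 CPM, 5.09-fold lower (4.52 to 5.73). Most RNA of Ccl24, Inhba and Cdh1 lay in cluster 4, a smaller part of the class in the E2 library, and within it their log2 ratios were -0.95, -1.28 and -1.15, against -1.99, -1.69 and -1.93 in the class. In that cluster AA467197, Slc7a2 and Timp1 lay at -0.29, -0.69 and -0.66, against -1.49, -1.48 and -1.44 in the class. Cxcl3, Pdpn, Mmp13 and Hilpda lay at -0.88, -1.68, -1.40 and -1.09 there. Ccl24, AA467197, Slc7a2, Cxcl3, Pdpn and Mmp13 are themselves leading genes of cluster 4. After thinning to 2000 UMIs, 22.0% of 842 placebo cells (19.2 to 24.9%) and 6.20% of 1870 E2 cells (5.15 to 7.39%) had an Arg1 UMI. The unthinned shares were 28.9% and 12.3%. In T-like cells, which should lack Arg1, the thinned shares were 0 of 967 placebo cells, which allows a share of up to 0.381%, and 0.749% of E2 cells. The median depths were 9173 and 9277 UMIs for monocyte/macrophage-like cells and 4391 and 4136 for T-like cells. Thinning left out 41 placebo and 47 E2 monocyte/macrophage-like cells.

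**Figure D2:**
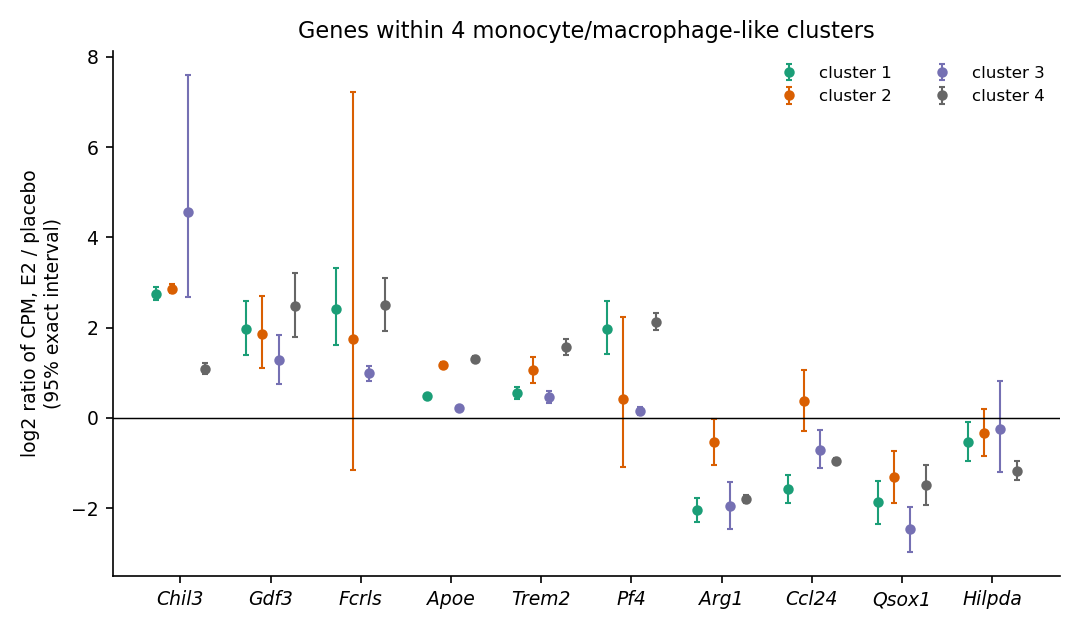
Log2 ratio of CPM, E2 over placebo (y axis), of 10 genes in the 4 largest monocyte/macrophage-like clusters (colours), with exact 95% intervals from counting error; no pseudocount was added. Chil3, Gdf3 and Trem2 lie above 0 and Qsox1 lies below 0 in each of the 4 clusters.

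Genes of the response to interferon-gamma, the cytokine of activated T and NK cells, were lower in the E2 library in these cells. Of 21 measured members 17 were lower, the median log2 ratio was -0.20, and 0.09% of matched random lists lay lower. Socs1, a feedback inhibitor of cytokine signalling, was at 46.7 and 20 CPM, and Cd274, which encodes PD-L1, at 37.4 and 17.8 CPM, both more than 2-fold lower. Ciita, the master regulator of MHC class II genes, was at 76.9 and 36.4 CPM, 2.11-fold lower (1.89 to 2.36). Cxcl9, a chemokine for T cells, went the other way, at 7.82 and 17.4 CPM, but its UMIs came from 9 of 883 placebo and 13 of 1917 E2 cells, 1.02% and 0.678%. The MHC class II list, the machinery that shows antigen to CD4 T cells, had 11 of 12 members lower and a median of -0.29 (percentile 0.05), with H2-Ab1 at 4380 and 3234 CPM and H2-Aa at 3983 and 2952 CPM. The type I interferon list was evenly split, 12 higher and 12 lower, with a median of -0.013.

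The hypoxia and glycolysis list had 26 of 27 members lower in the E2 library, 8 of them by at least 1.5-fold, with a median of -0.42, below all 10000 random lists. Egln3, an oxygen-sensing hydroxylase, was at 27.3 and 6.66 CPM, 4.10-fold lower (3.27 to 5.16). Hilpda, a hypoxia-induced lipid droplet protein, was at 93.6 and 31.0 CPM, and Slc2a1, the main glucose transporter, at 103 and 50.2 CPM. The angiogenesis and matrix remodelling list had a median of -0.42 as well, with 13 of 20 members lower. Of these, Mmp14, a membrane-bound matrix protease, was at 170 and 78.6 CPM, and Hbegf, a growth factor of the EGF family, at 51.8 and 15.3 CPM. Lipid-handling and lysosomal genes had a median of 0.21, with 14 of 22 higher, above all random lists, and Gpnmb, a lysosomal glycoprotein, was at 11.1 and 28.4 CPM. The complement C1q and phagocytic receptor list had a median of 0.26 with 12 of 18 higher, and C1qb, part of the first complement component, was at 802 and 1587 CPM. The alternative activation list was mixed: its median was 0.14, with 10 of 18 higher, its mean was -0.027, and Chil3 and Arg1 lay at its opposite ends. The classical activation list had a median of -0.12 with 11 of 16 lower, and Il1a, which encodes interleukin 1 alpha, was at 26.6 and 8.75 CPM. Oxidative phosphorylation genes had a median of 0.077 (percentile 91.6), with 23 of 28 higher, and the dissociation and immediate-early stress list 0.042, with 15 of 24 higher.

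With the same cluster mix in both libraries, a description chosen after seeing the data, the medians were -0.095 for hypoxia and glycolysis, -0.06 for matrix remodelling, -0.038 for C1q and phagocytic receptors, -0.17 for alternative activation and 0.035 for classical activation, which lay at 0.39 in cluster 1 and 0.42 in cluster 3. The interferon-gamma, MHC class II and lipid-handling lists lay at -0.25, -0.21 and 0.14 under that mix. Cluster 28 (14 placebo and 51 E2 cells), led by type I interferon genes such as Ifit3 and Isg15, is left out of that mix. MHC class II was at -0.086 with every cell thinned to 2000 UMIs and at -0.063 with the unnamed clusters of usual depth added. In cluster 4 it lay at 0.11.

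T-like cells of the E2 library had less RNA of interferon-gamma response and cytotoxic genes and more of proliferation genes. Tnfrsf9, the activation receptor 4-1BB, was at 424 and 232 CPM, 1.83-fold lower (1.70 to 1.97). Stmn1, a microtubule regulator of dividing cells, was at 175 and 345 CPM, 1.97-fold higher (1.82 to 2.14). All 20 measured members of the interferon-gamma list were lower, 6 of them by at least 1.5-fold, with a median of -0.48, below all 10000 random lists. Irf1, an interferon-induced transcription factor, was at 269 and 160 CPM, and Gbp2, a guanylate-binding defence protein, at 47.2 and 27.5 CPM.

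The cytotoxic effector list in T-like cells had 16 of 18 members lower and a median of -0.36, and the granzyme gene Gzma was at 35.4 and 10.8 CPM, 3.28-fold lower (2.38 to 4.59), with 60.2 times the T-like level in NK-like cells. The inhibitory receptor and exhaustion list had 15 of 16 lower and a median of -0.17 (percentile 5.4), and Lag3, an inhibitory receptor, was at 49.1 and 17.0 CPM, 2.90-fold lower (2.24 to 3.78). Regulatory T cell genes had a median of -0.24 with 11 of 14 lower, and Il10, an anti-inflammatory cytokine, was at 35.6 and 15.4 CPM. The type I interferon list lay at -0.14 with 18 of 21 lower, and the hypoxia and glycolysis list at -0.15 with 19 of 27 lower. Proliferation genes had 23 of 26 members higher and a median of 0.47, above all random lists, with Birc5, a mitotic survivin, at 57.1 and 109 CPM. Oxidative phosphorylation genes had 27 of 28 higher and a median of 0.22, and the stress list lay at 0.015 with 13 of 24 higher. Among the other genes with the largest ratios, Tmem176b, Hist1h1e, Il2 and Hist1h1b lay at 0.83 to 0.96 and Il13, Ccl4, Penk and Rnf157 at -2.34 to -0.74. Il13 (chromosome 11, 53631324 to 53634702, minus strand) was at 83.9 and 8.59 CPM, 9.77-fold lower (7.03 to 13.9). ILC2-like cells, which were less frequent in the E2 library, held 725 CPM of Il13, 14.8 times the T-like level. Basophil-like cells, also less frequent, held 33154 CPM of the chemokine gene Ccl4, 822 times the T-like level.

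Of the T-like clusters, the cycling cluster 27 held 24 placebo and 44 E2 cells. The same cluster mix leaves this cluster out, since it has too few placebo cells. Also left out are the small CD8 T-like cluster 30 (28 placebo and 24 E2 cells) and gamma-delta T-like cluster 31 (24 and 17). Under that mix the proliferation median was 0.0097 and the cytotoxic median -0.16. These medians therefore do not show what an equal share of cycling cells would give. The proliferation median was 0.0028 with 3 times as many doublets removed and 0.079 with every cell thinned to 2000 UMIs, while Il2, which encodes the T cell growth factor interleukin 2, went from 0.91 to -0.31 with at least 500 genes per barcode.

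The lists were also read within the T-like subsets, and differences between subsets were not tested. In regulatory T-like cells all 18 measured interferon-gamma members were lower, with a median of -0.62, and 13 of 14 exhaustion members were lower, with a median of -0.29. Foxp3, the defining transcription factor of these cells, was at 761 and 559 CPM, and Il2ra, the interleukin 2 receptor alpha chain, at 1281 and 914 CPM. The regulatory T cell list had a median of -0.24 in this subset, with 11 of 14 lower. CD4 T-like cells had medians of -0.22 for interferon-gamma, with 13 of 16 lower, and -0.38 for exhaustion, with 9 of 10 lower. There Pdcd1, which encodes PD-1, was at 25.4 and 47.7 CPM and went the other way, 1.88-fold higher (1.12 to 3.19). CD8 T-like cells had a cytotoxic median of -0.35, with 11 of 15 lower, and a proliferation median of -0.52, with 14 of 15 lower. That subset leaves out the cycling cluster 27, so its proliferation median covers only cells not clustered as cycling. In these cells Gzmb, the granzyme B gene, was at 278 and 142 CPM, 1.97-fold lower (1.53 to 2.56), and Pcna, a DNA replication clamp, at 184 and 108 CPM. After thinning, 19.0% of 179 placebo and 12.4% of 113 E2 cells had a Gzmb UMI, with overlapping intervals (13.5 to 25.5% and 6.94 to 19.9%). In CD8 T-like cells the interferon-gamma median of -0.16 lay at percentile 25.9 of random lists and did not stand apart. Their exhaustion list had a median of 0.02, 6 higher and 6 lower, and a mean of -0.25, with Lag3 at 22.8 and 3.50 CPM. After thinning, 10.1% of 179 placebo and 15.9% of 113 E2 CD8 T-like cells had a UMI of Ifng, the interferon-gamma gene, with overlapping intervals (6.07 to 15.4% and 9.72 to 24.0%). Among monocyte/macrophage-like cells, which should lack it, 0 of 842 and 0 of 1870 had an Ifng UMI at that depth. The unthinned Ifng shares were 24.0% and 22.3%, at median depths of 4736 and 4417 UMIs, and thinning left out 4 placebo and 8 E2 cells.

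Neutrophil-like cells of the E2 library had more RNA of type I interferon and oxidative phosphorylation genes and less of interferon-gamma response genes. Ly6g (chromosome 15, 75155240 to 75159126, plus strand), the surface marker of mouse neutrophils, was at 18.0 and 161 CPM, 8.97-fold higher (4.94 to 18.2). Retnlg, a secreted resistin-like protein of neutrophils, was at 2134 and 8044 CPM, 3.77-fold higher (3.56 to 3.99). Prok2, a chemotactic peptide gene, the metallothionein gene Mt1, BC100530 and Cxcr1, a chemokine receptor gene, lay at log2 ratios of 1.88 to 2.71. Cxcl10, an interferon-induced chemokine, was at 134 and 11.7 CPM, 11.4-fold lower (7.01 to 19.5), and Havcr2, which encodes TIM-3, at 126 and 8.37 CPM. Acp5, Inhba, Ikbke and Olr1 lay at -3.09 to -2.16, with Acp5 resting on 52 and 2 UMIs. Within cluster 8, the largest of the class, Ly6g lay at 2.70, Prok2 at 3.11, Cxcl10 at -2.74, Inhba at -2.57 and Olr1 at -2.54. Havcr2, at 10.4 and 0.952 CPM, Acp5, at 3.47 and 1.90 CPM, and Ikbke, at 13.9 and 4.76 CPM, were low there in both libraries, and their ratio intervals included 1.

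In the neutrophil-like class 9 of 10 interferon-gamma members were lower, with a median of -0.70 (percentile 0.04), and Cd274 was at 275 and 73.6 CPM. Type I interferon genes lay the other way, at a median of 0.29 with 15 of 20 higher, and Rtp4, an interferon-induced chaperone, was at 63.7 and 178 CPM. The hypoxia and glycolysis list had a median of 0.18 with 18 of 26 higher, oxidative phosphorylation 0.36 with 26 of 28 higher, and matrix remodelling 0.40 with 7 of 12 higher and a mean of 0.034. In the last list Thbs1, the matrix protein thrombospondin 1, was at 2098 and 4287 CPM while Spp1, the secreted phosphoprotein osteopontin, was at 1132 and 451 CPM. Lipid-handling genes had a median of -0.46 with 11 of 17 lower, including the cathepsin gene Ctsz at 449 and 119 CPM, and the stress list -0.35 with 20 of 24 lower. The class held clusters 8 (107 placebo and 262 E2 cells), 9 (93 and 261) and 26 (58 and 19), so cluster 26, with median depth 1983 UMIs, came mostly from the placebo library. Retnlg leads cluster 8, and its log2 ratio of 1.91 was 1.57 with the same cluster mix, which leaves out cluster 26. Within cluster 8 the interferon-gamma median was -0.47, with 6 of 8 lower, and the lipid-handling median was 0.031, with 9 of 16 higher, so the lower lipid-handling median of the class was not seen there.

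The cDC2-like cells of the E2 library had more MHC class II and type I interferon RNA and less RNA of maturation genes. The MHC class II list had 10 of 12 members higher and a median of 0.18 (percentile 99.6), with H2-Eb1 at 8720 and 11573 CPM and Cd74, the class II invariant chain, at 22417 and 29577 CPM. Type I interferon genes had 17 of 22 higher and a median of 0.31, while 11 of 16 interferon-gamma genes were lower, with a median of -0.32 (percentile 0.05). Dendritic cell maturation genes had 13 of 17 lower and a median of -0.24, and Il4i1, an amino acid oxidase of mature dendritic cells, was at 158 and 63.7 CPM, 2.48-fold lower (2.08 to 2.96). Proliferation genes had 17 of 20 higher and a median of 0.38, with Stmn1 at 18.1 and 82.6 CPM, 4.57-fold higher (3.07 to 7.08). The hypoxia and glycolysis list was split 13 to 13 with a median of 0.0081 and a mean of -0.0041. Oxidative phosphorylation had a median of 0.097 (percentile 97.2) with 21 of 28 higher, and the stress list lay at 0.026 with 13 of 24 higher. Among the other genes with the largest ratios, C1qa, Clec4b1, C1qb, Clec4n and Ccrl2 lay at 1.24 to 1.97, and Ifi202b, Atp2b4, Qsox1, Areg and Ifitm1 at -1.78 to -1.23. Monocyte/macrophage-like cells held 17.8 and 12.4 times as much C1qa and C1qb as this class. ILC2-like cells held 22.7 times as much Areg and basophil-like cells 21.6 times as much Ifitm1, and both classes were less frequent in the E2 library. With every cell thinned to 2000 UMIs, Clec4n lay at -0.033.

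NK-like cells of the E2 library had less RNA of the tissue-residence gene Itgae and of naive and memory genes and more of some granzymes and cell cycle genes. Itgae (chromosome 11, 73090583 to 73147446, plus strand), the integrin chain CD103, was at 343 and 38.8 CPM, 8.84-fold lower (6.35 to 12.6). The naive and memory list had 9 of 10 members lower and a median of -0.69, below all random lists, with Tcf7, a transcription factor of memory and immature lymphocytes, at 267 and 117 CPM. The cytotoxic effector list had a median of 0.19 with 11 of 18 higher. Its members went both ways: Gzmf was at 9.19 and 74.0 CPM, 8.05-fold higher (3.55 to 22.6), and Gzmb at 196 and 348 CPM, while Gzmc was at 3333 and 1876 CPM, 1.78-fold lower (1.67 to 1.89). Proliferation genes had 13 of 17 higher and a median of 0.51, with Mki67, a marker of dividing cells, at 19.9 and 46.0 CPM. Interferon-gamma genes had a median of -0.29 with 10 of 14 lower (percentile 5.45), oxidative phosphorylation 0.23 with 27 of 28 higher, hypoxia and glycolysis -0.075 with 13 of 24 lower, and the stress list -0.18 with 16 of 23 lower. After thinning, 10.0% of 100 placebo cells (4.90 to 17.6%) and 26.2% of 141 E2 cells (19.2 to 34.3%) had a Gzmb UMI, against 0.594% and 0.0535% of monocyte/macrophage-like cells. The NK-like median depths were 5746 and 6805.5 UMIs, and thinning left out 4 placebo cells and 1 E2 cell. The other genes with the largest ratios were Tmsb15a, Apoe, AA467197, Socs2 and Magohb at 1.39 to 2.82 and Areg, Pacsin1, Ccnd1, Cxcl2 and Baiap2 at -2.80 to -1.77. Areg, a growth factor of the EGF family, rested on 43 and 1 UMIs, a 73.0-fold lower level with an interval from 12.4 to 2948. ILC2-like cells, which were less frequent in the E2 library, held 50.5 times the NK-like level of Areg. Monocyte/macrophage-like cells held 93.5 times the NK-like level of Apoe, and neutrophil-like cells 1022 times that of Cxcl2, which lay at 0.61 with no doublet removal. The class held 104 placebo and 142 E2 cells, and the median log2 ratio of all its genes was -0.11.

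**Figure D3:**
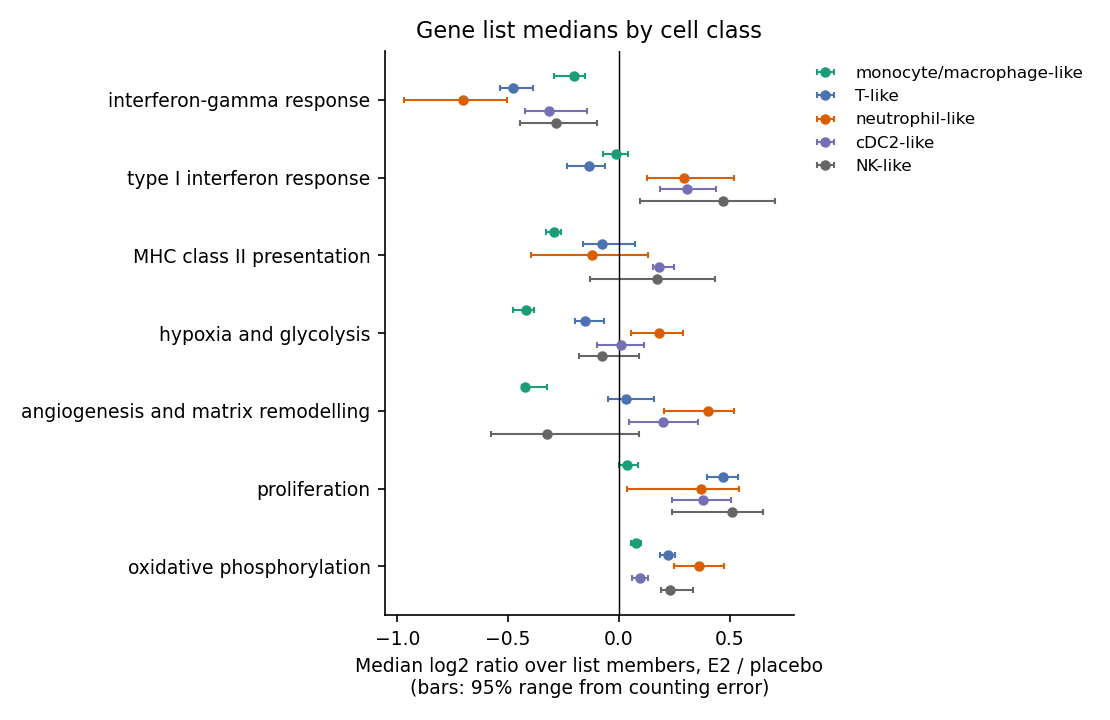
Median log2 ratio, E2 over placebo (x axis), over the measured members of 7 gene lists in 5 cell classes (colours), with the 95% range that counting error gives. The interferon-gamma medians lie below 0 in all 5 classes, from -0.70 in neutrophil-like to -0.20 in monocyte/macrophage-like cells. The oxidative phosphorylation medians lie above 0 in all 5, within the middle 95% of random lists in monocyte/macrophage-like and cDC2-like cells. Ribosomal protein genes, not plotted, also had medians above 0. They were 0.088 in monocyte/macrophage-like, 0.16 in T-like, 0.15 in neutrophil-like, 0.16 in cDC2-like and 0.18 in NK-like cells. Whether both lists share a cause was not tested.

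The receptors for estrogen were little detected. Esr1 (chromosome 10, 4611593 to 5005614, plus strand), the gene of estrogen receptor alpha, had 64 UMIs in the placebo library and 177 in the E2 library. In monocyte/macrophage-like cells Esr1 was at 5.29 CPM (3.85 to 7.10) and 5.28 CPM (4.28 to 6.45). In mast-like cells it was at 17.5 CPM (7.53 to 34.4) and 10.1 CPM (5.96 to 15.9). Esr2, the gene of estrogen receptor beta, had 0 UMIs in both libraries, and Gper1, the gene of the G protein-coupled estrogen receptor, had 3 and 4. Both libraries held the female-specific transcript Xist, at 816 and 723 CPM, and at most 6 UMIs of any of 4 Y-linked genes.

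Markers of cells outside the sort were read in all kept barcodes. The fibroblast markers summed to 729 CPM (718 to 740) in the placebo library and 1215 CPM (1205 to 1225) in the E2 library, and the endothelial markers to 6.95 and 27.5 CPM. In the named immune classes alone the fibroblast markers were at 11 and 27.6 CPM and the endothelial markers at 5.19 and 5.28 CPM. Epithelial markers were at 114 and 47.5 CPM, a list that includes Cdh1, which the monocyte/macrophage-like cells also expressed. Melanocytic markers were at 37.0 and 58.3 CPM, of which 34.1 and 55.1 CPM remained in the named immune classes alone. Most of that sum was Mitf, Syngr1 and Slc24a5, while the pigment genes Pmel, Mlana, Tyr, Tyrp1 and Dct were each at 0.944 CPM or lower. Platelet markers were at 20.7 and 18.1 CPM, of which Itga2b made up 19.3 and 16.2 CPM, and erythroid markers were at 2.19 and 6.95 CPM.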

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

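Of the tests in this part, those of transcript length and of bone marrow were chosen before their result was seen, and all the others were chosen after.

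Several gene lists lay on opposite sides of 0 in different cell classes, and none of these differences between classes was tested. The MHC class II median was 0.18 in cDC2-like and -0.29 in monocyte/macrophage-like cells, 0.47 apart. The monocyte/macrophage-like value was -0.086 with every cell thinned to 2000 UMIs and -0.063 with the unnamed clusters of usual depth added, and cluster 4 alone lay at 0.11. The hypoxia and glycolysis median was 0.18 in neutrophil-like and -0.42 in monocyte/macrophage-like cells, 0.60 apart. The angiogenesis and matrix remodelling median was 0.40 and -0.42 in the same classes, 0.83 apart, but the neutrophil-like mean was 0.034. With the same cluster mix the monocyte/macrophage-like medians were -0.060 for matrix remodelling and -0.095 for hypoxia and glycolysis. Lipid-handling genes lay at 0.25 in cDC2-like and -0.46 in neutrophil-like cells, 0.71 apart, but at 0.031 within neutrophil-like cluster 8. Chemokine genes lay at 0.25 in cDC2-like and -0.23 in T-like cells, 0.48 apart. Proliferation genes lay at 0.51 in NK-like and -0.52 in CD8 T-like cells, 1.03 apart, but the CD8 T-like subset leaves out the cycling T-like cluster 27, with 24 placebo and 44 E2 cells, and the NK-like class has no such split. How far that difference depends on the clustering of dividing cells was not tested.

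The unnamed clusters of usual depth were outside the comparisons of cell classes and held more of the E2 barcodes. Cluster 7 was 5.49% of E2 and 2.83% of placebo barcodes. It combined Csf1r, the receptor for the macrophage growth factor, at 452 CPM with C1qa at 2358 CPM. Cluster 22, in which Top2a and Mki67 of dividing cells were among the leading genes, was 1.73% and 0.619%. Cluster 34 was 0.564% of E2 barcodes (0.383 to 0.80%) and 0 of 3392 placebo barcodes, which allows a share of up to 0.109%. Its leading genes Ctsk, Acp5, Mmp9 and Atp6v0d2 are known from osteoclasts, the bone-resorbing relatives of macrophages, and no class of that kind was among the marker lists.

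The hypoxia and glycolysis list in monocyte/macrophage-like cells, at -0.42, was weighed against technical and biological explanations. A difference in depth between the libraries was argued against, since the median was -0.44 with every cell thinned to 2000 UMIs. A different mix of clusters is a candidate explanation: with the same cluster mix the median was -0.095, at percentile 26.9 of random lists. Cluster 4, which held 280 placebo and 219 E2 cells, had a median of -0.34 on its own. An action of estradiol on the mice cannot be told apart from any other difference between the hosts or the preparations, with 1 library per group.

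The interferon-gamma response list in T-like cells, at -0.48, had every measured member lower. A different mix of clusters was argued against as the whole cause, since the median was -0.44 with the same cluster mix, below all random lists. That mix leaves out the small T-like clusters 27, 30 and 31, so it does not cover their part. Transcript length was argued against as well, since the middle 95% of random lists matched on expression and length ran from -0.19 to 0.018. A biological difference between a host with and a host without estradiol may be behind it, such as less interferon-gamma reaching the cells. With 1 library per group such a difference cannot be told apart from other differences between the libraries. After thinning, 4.03% of placebo and 4.87% of E2 T-like cells had an Ifng UMI. In NK-like cells the shares were 8.0% and 9.22%, and the intervals overlapped in both classes. A lower Ifng share was therefore not seen there, and the protein was not measured.

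A B-like cluster led by Vpreb3 held 108 placebo and 3 E2 cells, a log2 ratio of shares of -5.87 (-8.42 to -4.53). With no doublet removal, the B-like cluster with the fewest E2 barcodes held 116 placebo and 3 E2 barcodes, a log2 ratio of -6.00. That cluster was picked by its E2 count, so E2 cells returned to another B-like cluster would not show. Removal of such cells as doublets in the E2 library is therefore not excluded. Bone marrow carried into the placebo dissociation may be a source of the cells of the Vpreb3-led cluster and stays open. Granulocyte precursors, called by Elane, Mpo and Ctsg, were 0.0884% of placebo barcodes (0.0182 to 0.258%) and 0.0546% of E2 barcodes, 3 barcodes in each. An action of estradiol, which is known to lower B cell formation in mouse marrow, cannot be told apart from a difference in dissection with 1 library per group.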

How the results depend on the processing

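Of the alternatives here, 3 were chosen after seeing the data: adding unnamed clusters, shares among named immune classes, and the same cluster mix. Values are log2 ratios or list medians of log2 ratios, E2 over placebo, and the cause was not tested for any change below except that of the B-like share. Over the alternatives, the mitochondrial limits left out, 1621 values stayed within their counting interval, 438 moved by more, and 17 whose counting interval excluded 0 changed sign and are called reversed. Among log2 ratios of shares 145 stayed within and 13 left their interval, and the unnamed share, whose interval included 0, changed sign at Leiden resolution 0.5 and with unnamed clusters added. Among list medians 726 stayed, 148 left and 8 reversed, and among named genes 708, 219 and 9. Percents of cells with a UMI were read again only at 1000 UMIs and without thinning, where 42 stayed and 58 left. Such a percent changes with depth by construction. These 58, which the 438 include, therefore say nothing about stability.

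With at least 500 genes per barcode the unnamed share was at 0.86, the non-immune share at 1.09, MHC class II in monocyte/macrophage-like cells at -0.20 and Il2 in T-like cells reversed to -0.31. With no doublet removal the B-like share was at -1.02, alternative activation at 0.054, and Cxcl2 in NK-like cells reversed to 0.61. With the automatic Scrublet threshold the B-like share was at -1.26; under both settings a further, shallow cluster took the B-like name, with 79 placebo and 158 E2 barcodes and with 75 and 120, while the other B-like clusters held 116 and 3 and 66 and 52. The automatic threshold put alternative activation at 0.21 and T-like proliferation at 0.54. With 3 times as many doublets removed the basophil-like share was at -3.94, alternative activation at 0.30, classical activation at -0.061, type I interferon at -0.11, hypoxia at -0.38 and C1q at 0.19 in monocyte/macrophage-like cells. In T-like cells exhaustion was then at -0.087, proliferation at 0.0028 and Il2 reversed to -0.19.

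At Leiden resolution 0.5 the unnamed share was at -0.047, the gamma-delta share of T-like cells at 0.11, MHC class II in monocyte/macrophage-like cells at -0.22, and in T-like cells interferon-gamma at -0.36 and cytotoxic genes at -0.23. ILC2 and CD4 T-like cells were not named at that resolution and have no value there. With every cell thinned to 2000 UMIs before clustering, the shares of T-like, unnamed, neutrophil-like and cDC2-like cells were at -1.04, 1.12, 0.68 and 0.62. In monocyte/macrophage-like cells thinning gave classical activation -0.35, type I interferon -0.099, interferon-gamma -0.35, MHC class II -0.086, lipid handling 0.12, matrix remodelling -0.50 and C1q 0.17, and it reversed alternative activation to -0.073 and stress to -0.018. It gave T-like proliferation 0.079 and reversed Il2 in T-like cells to -0.25, Clec4n in cDC2-like cells to -0.033 and the estrogen target list in CD4 T-like cells to 0.052.

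With median of ratios scaling, monocyte/macrophage-like alternative activation was at 0.22, MHC class II at -0.21, hypoxia at -0.34, lipid handling at 0.29 and C1q at 0.31, and T-like interferon-gamma was at -0.38, exhaustion at -0.074 and proliferation at 0.56. Without ribosomal and mitochondrial genes C1q was at 0.30. With a pseudocount of 1 CPM, classical activation was at -0.20, interferon-gamma at -0.41 and MHC class II at -0.33 in monocyte/macrophage-like cells, and interferon-gamma at -0.59 and cytotoxic genes at -0.45 in T-like cells. With cells weighted equally, monocyte/macrophage-like classical activation was at -0.25, interferon-gamma at -0.30, MHC class II at -0.25, lipid handling at 0.095, matrix remodelling at -0.44 and C1q at 0.20, alternative activation reversed to -0.068, and Ccl8 reversed to -0.28. T-like cytotoxic genes were then at -0.25, exhaustion at -0.081 and proliferation at 0.25. With a gene minimum of 100 UMIs interferon-gamma was at -0.31 and matrix remodelling at -0.47 in monocyte/macrophage-like cells, and with a minimum of 1 MHC class II was at -0.25.

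With the unnamed clusters of usual depth added, the monocyte/macrophage-like share was at 0.53 and the unnamed share at -1.05. In that class classical activation was at -0.24, MHC class II at -0.063, hypoxia at -0.34, lipid handling at 0.15, matrix remodelling at -0.21 and C1q at 0.21, and stress reversed to -0.056. With the same cluster mix, MHC class II was at -0.21, hypoxia at -0.095, lipid handling at 0.14 and matrix remodelling at -0.060, and reversed were alternative activation to -0.17, classical activation to 0.035, C1q to -0.038, Ccl8 to -0.23 and Gas6 to -0.080. In T-like cells that mix gave cytotoxic genes -0.16 and proliferation 0.0097, and reversed Hist1h1b to -0.49. This mix leaves out monocyte/macrophage-like cluster 28, T-like clusters 30 and 31 and the cycling T-like cluster 27. Each has fewer than 30 cells in a library. These T-like values therefore cover only cells not clustered as cycling.

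At Leiden resolution 2.0 the 31 shares and list medians that answer the comparisons stayed within their counting intervals, and so did 16 shares among named immune classes. The limits of 5% and 20% mitochondrial UMIs removed no barcode, since those genes held 0 UMIs, and say nothing about stability. Depth limits the rare classes: basophil-like cells rested on 109 placebo and 30 E2 cells and NK-like cells on 104 and 142. The intervals cover counting error only, and no alternative replaces a replicate library.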

Other observations

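Of what follows, only the estrogen target list was chosen before its result was seen, and the same cluster mix and the genes of the B-like clusters were chosen after.

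Genes that estrogen is known to induce in breast and uterine cells were read in each class, and differences between classes were not tested. The list of estrogen receptors and classical targets had a median log2 ratio of -0.12 in monocyte/macrophage-like cells, with 6 of 9 members lower (percentile 20 of random lists), and of -0.11 in T-like cells, with 8 of 11 lower (percentile 30). In cDC2-like cells 8 of 8 members were lower, with a median of -0.25 (percentile 6.19), and in regulatory T-like cells 7 of 8 were lower, with a median of -0.30 (percentile 0.5). CD4 T-like cells had 6 of 7 lower and a median of -0.30 (percentile 4.13), which was 0.052 with every cell thinned to 2000 UMIs. In CD8 T-like cells 4 of 7 were higher, with a median of 0.12 (counting range -0.17 to 0.37), and in NK-like cells 4 of 7 were higher, with a median of 0.00032 (-0.34 to 0.095) and a mean of -0.41. In neutrophil-like cells 3 members were measured and 3 were lower. Rara, the retinoic acid receptor alpha gene, was lower in the monocyte/macrophage-like, T-like, cDC2-like and regulatory T-like cells, at 124 and 88.1 CPM in monocyte/macrophage-like, 98.9 and 71.6 CPM in T-like, 118 and 73.8 CPM in cDC2-like and 116 and 72.4 CPM in regulatory T-like cells. Igfbp4, a binding protein of insulin-like growth factors, went both ways, at 49.4 and 82.3 CPM in monocyte/macrophage-like cells and at 36.2 and 11.9 CPM in cDC2-like cells. Tff1, a trefoil peptide gene induced by estrogen in epithelium, was at 230 and 168 CPM in regulatory T-like cells. With the same cluster mix, 9 of 9 members were lower in monocyte/macrophage-like cells, with a median of -0.25 (percentile 1.16). In T-like cells 8 were lower and 3 higher under that mix, with a median of -0.082 (percentile 34.9).

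The B-like cells fell into cluster 21, with 66 placebo and 52 E2 cells, and cluster 24, the Vpreb3-led cluster. Rag1, which rearranges antigen receptor genes in developing lymphocytes, had a UMI in 38 of the 111 cells of cluster 24, and the proliferation marker Mki67 had a UMI in 12 of them. In cluster 21 both had 0 UMIs, which allows up to 8.83 CPM. Ighd, the heavy chain gene of mature naive B cells, was at 339 CPM in cluster 24 and 1319 CPM in cluster 21. Dntt, an enzyme of early B cell precursors, had 0 UMIs in cluster 24, which allows up to 7.59 CPM. Vpreb1 and Igll1 had a UMI in 7 and 4 of the 111 cells of cluster 24. Igkc, a light chain gene, had a UMI in 102 and Ms4a1 in 78 of them, against 113 and 109 of the 118 cells of cluster 21.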
